A study of Lactococcus cremoris with 16 samples.

How the data were processed

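Total RNA of *Lactococcus cremoris* MG1363 and derivatives was labelled with Cy3 and with Cy5 after reverse transcription with allyl-modified dUTP, per the labels' protocols, and measured on microarrays whose type, scanner and image software are not given in the sources used here. The 16 samples are 8 cultures, each labelled with both dyes, and fall into 4 groups of 2 cultures. Groups and replicate numbers came from the sample labels. The 2 samples of a culture were averaged and counted as 1 replicate, so that n = 2 in every group. The labels call the cultures biological replicates. No 2 cultures held an identical value for any feature.

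The deposited raw table holds 1 intensity column per sample, per the file headers, with 15208 rows for 2633 features. Of these features, 2043 have 6 rows and 590 have 5. Neither the header nor the labels say whether background was subtracted, and the scale of the intensity is unknown. Column medians ran from 4.79 to 11.9, the values were not whole numbers, and 1 value was an exact 0. From these properties the intensity was taken as already background corrected, and no correction was applied. The plan made before the data were examined asked for a normexp correction with an offset of 50 only for uncorrected signal. Whether the signal was corrected was judged from its values, which do not settle it. The lowest value of some columns lay far above 0, so background may remain in them. It was 6.00 beside a median of 11.9 in the IS905 integrant at OD600 0.3 replicate 1 (Cy3). In wild type replicate 2 (Cy3) it was 4.74 beside 10.6. Other columns reached close to 0, such as 0.11 beside 5.96 in IS905 integrant replicate 2 (Cy3). The planned correction for uncorrected signal, normexp together with an offset of 50, left no feature past the threshold in any comparison with the wild type. Normexp without the offset gave 5, 7 and 9 calls there, so the loss went with the offset, which is large beside the column medians. The number of arrays limits the precision of every value.

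The deposited processed table holds 1 score per feature and sample, with steps and scale not given in the sources used here. Set against the raw intensity, the logarithm of each score was close to proportional to the logarithm of the median over the feature's rows (r across features between 0.984 and 0.999). In other words, the score was near that median raised to a power between 2.78 and 4.48 that differed between columns. Between 70.4% and 80.3% of features lay within 0.05 (log2) of that relation. Column medians were 974.1 and 980.5 (wild type replicate 2, Cy3 and Cy5), 1024 and 992.3 (wild type replicate 1), 967.6 and 998.6 (IS905 integrant replicate 1) and 1034.8 and 997 (IS905 integrant replicate 2). They were 961.1 and 943.3 (IS905 integrant at OD600 0.3 replicate 1), 999.5 and 969.7 (its replicate 2), 945.8 and 974.2 (gfp integrant replicate 1) and 997.1 and 987.4 (gfp integrant replicate 2). Fold changes on this scale are stretched by the power, so the table served only as an alternative. The direction of the values is that of the raw intensity.

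The 16 intensity columns were quantile normalised, converted to log2, and summarised as the median over the rows of a feature and then as the mean of the 2 dyes of a culture. Rows of 1 feature carry no probe name, so spots and probes could not be told apart. Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes over all 8 cultures, with no replicate block. Tests were two-sided, with Benjamini-Hochberg adjustment over 2633 features and calls at an adjusted p under 0.05. Each comparison of an integrant with the wild type joins the integration with the loss of celB, ptcC and llmg_0963, if the wild type is MG1363 with none of these changes, as the sample labels have it. The series description instead speaks of a comparison with the original strain, which can also be read as the deletion strain. The sample labels were followed. Comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The offset of 50 on the deposited signal, and leaving out cultures for blocks of consecutive locus numbers, were added afterwards. The rule took the genes that check the labels, every called feature within 10 locus numbers of llmg_1239, and the called features with the largest differences whose cultures did not overlap. It also took up to 2 called members of each other list.

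Features are named by locus tags, which the tables do not pair with gene names. The gene table used here holds 2360 genes and matched 0 of the locus tags, so no gene symbol was assigned. Of 20 gene lists, 19 had fewer than 3 members that could be found and were not tested. The list tested is the neighbourhood of llmg_1239, llmg_1229 to llmg_1249 by locus number, of which 18 features were measured. celB and ptcC could not be located by name. llmg_1239 has 0 rows in the deposited raw table, so its signal could not be analysed. List tests used camera with a preset correlation of 0.01, with an estimated correlation and fry beside it. As 1 list was tested, its adjusted p equals its p.

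The fit was tested on simulated data with the observed means and spreads and 200 changed features among 2633. For the gfp integrant against the wild type it recovered 60% of features changed by 0.5 (log2) and 95.5% of those changed by 1, with 6.98% and 4.98% false calls. For the IS905 integrant against the wild type the recovered shares were 58% and 95.5%. These shares hold for a spread equal to the observed one in each feature and for 200 changed features. With fewer changed features the adjustment is stricter, and a smaller share would be recovered. At OD600 0.3, where 5 features were called against the wild type, llmg_1241 differed by 0.93 and did not pass (limma adjusted p of 0.106). Alternatives covered the background correction, the normalisation, the row summary, dim features, single dyes, the 16 samples with dye as a covariate, replicate blocks, the groups in the fit, the prior variance, a fold threshold, the processed table, and leaving out each culture.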

Results

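Transcript levels were measured in 4 groups of *Lactococcus cremoris* cultures grown at 30 °C in rich M17 medium with 1% cellobiose, a glucose disaccharide, as the carbon source. The wild type was MG1363, a plasmid-free laboratory strain. The other groups were cellobiose-positive derivatives of an MG1363 strain without celB, ptcC and llmg_0963, which carried either the insertion sequence IS905 or a gfp reporter gene in llmg_1239. IS905 integrant cultures formed 2 groups, one labelled with an OD600 of 0.3 and one with no density of its own. Harvest took place in mid-exponential phase, at an OD600 near 0.3 in some cultures and near 0.6 in others, per the labels. Each group held 2 cultures, each measured with Cy3 and with Cy5, for 2633 features. The median signal per sample ran from 4.79 to 11.9 on an unknown scale, and the 99th percentile was only 1.98 to 4.55 times the median. Any background left in such a narrow range makes fold changes understate differences in transcript level. Values are given as log2 of normalised signal.

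llmg_0963, deleted in the integrants, checks the labels. Its signal was 2.50 ± 0.04 in the wild type, 2.57 ± 0.15 in the IS905 integrant, 2.39 ± 0.08 in the IS905 integrant at OD600 0.3 and 2.49 ± 0.14 in the gfp integrant (mean ± SD, n = 2 each). In the wild-type cultures it lay at percentiles 9.34 and 8.58 of all features, so a loss of its transcript could not be seen on these arrays and the labels are neither borne out nor contradicted by it. Its adjusted p in limma was 0.992 in the IS905 integrant, 0.821 at OD600 0.3 and 0.992 in the gfp integrant.

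The gfp integrant was compared with the wild type to find the transcripts that differ when gfp sits in llmg_1239. It also lacks celB, ptcC and llmg_0963, and neither group has a density of its own in the labels. The differences therefore cannot be assigned to gfp alone. The features next to the integration site on its higher-numbered side gave a higher signal, with differences of 0.88 to 1.28 for llmg_1240 to llmg_1245 (1.84-fold to 2.42-fold). These 6 differences ran from 2.02 to 3.26 with normexp without offset, and from 0.14 to 0.20 when an offset of 50 was added to it. llmg_1242 rose by 1.28 (SE 0.19, 2.42-fold), from 2.50 ± 0.10 to 3.78 ± 0.33 (n = 2 each), with an adjusted p of 0.031 in limma. llmg_1245 rose by 1.23 (SE 0.15), llmg_1240 by 1.13 (SE 0.16) and llmg_1243 by 0.95 (SE 0.12), with adjusted p of 0.018, 0.026 and 0.018. llmg_1241 differed by 0.94 (SE 0.16) and llmg_1244 by 0.88 (SE 0.23), which did not pass (adjusted p of 0.099 and 0.522). The only feature called lower was llmg_0186, which went from 3.89 ± 0.34 to 2.70 ± 0.04, a difference of -1.19 (SE 0.15, adjusted p of 0.018). It was -2.78 with normexp without offset and -0.22 with the offset of 50. These 5 were all the calls among 2633 features, 4 higher and 1 lower. Of the 18 measured features of the llmg_1239 neighbourhood, 4 rose, 0 fell and 14 did not pass, and 8 rose when adjusted over the list alone. The list stood higher than the other features by camera (adjusted p = 2.4e-09 with the preset correlation, adjusted p = 0.024 with an estimated correlation), with a median difference of 0.22. The other 12 members ranged from -0.38 to 0.45. The count of calls was 0 without wild type replicate 2, without gfp integrant replicate 1 and without either culture of the IS905 integrant at OD600 0.3, which shares the estimate of the spread. It was 36 without wild type replicate 1 (4 higher and 32 lower), 2 without gfp integrant replicate 2, and 0 with a normexp offset of 50 or with Cy3 alone.

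**Figure D1:**
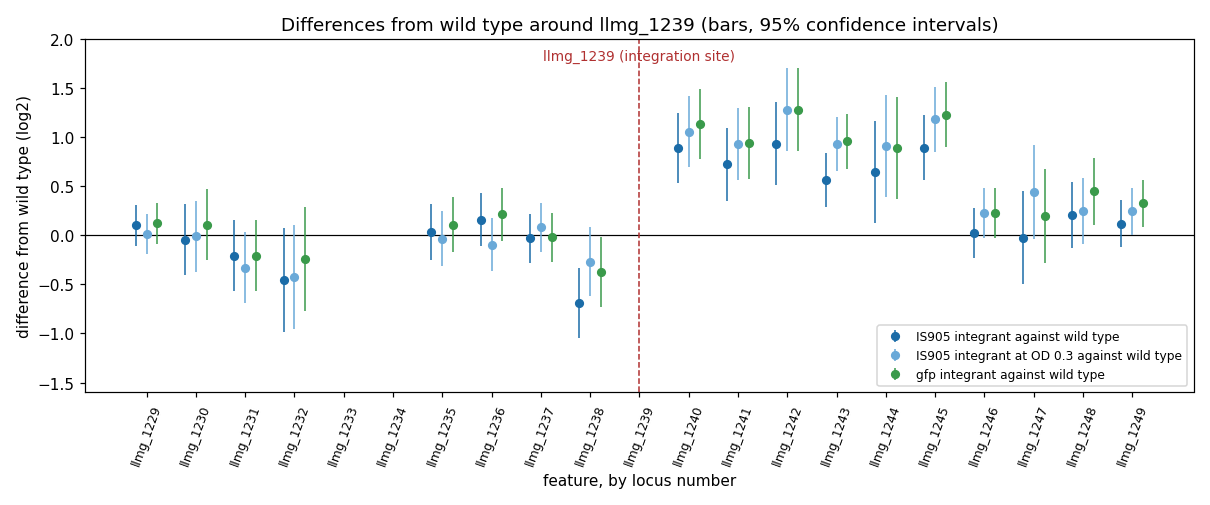
Difference from the wild type (log2, vertical axis) of the features llmg_1229 to llmg_1249 by locus number (horizontal axis) in the 3 integrant groups, with 95% confidence intervals from limma and the integration site as a dashed line. Points for llmg_1240 to llmg_1245 lie between 0.56 and 1.28 in all 3 comparisons, and the other 12 measured features lie between -0.69 and 0.45.

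The IS905 integrant at OD600 0.3 was compared with the wild type to ask the same of IS905. The wild-type cultures have no density of their own in the labels, so a difference in harvest density may be part of this comparison. The integrant also lacks celB, ptcC and llmg_0963, per the labels. For both reasons its calls cannot be assigned to IS905 alone. llmg_1242 rose by 1.27 (SE 0.19, 2.42-fold), from 2.50 ± 0.10 to 3.78 ± 0.02, llmg_1245 by 1.18 (SE 0.15), llmg_1240 by 1.05 (SE 0.16) and llmg_1243 by 0.93 (SE 0.12), with limma adjusted p of 0.038, 0.019, 0.038 and 0.021. llmg_1241 differed by 0.93 (SE 0.16, adjusted p of 0.106) and llmg_1244 by 0.91 (SE 0.23, adjusted p of 0.568). Among features whose cultures did not overlap with the wild type, the largest positive difference was that of llmg_1635 at 1.36 (SE 0.41, adjusted p of 0.568). It was singled out after the values were seen. llmg_0186 differed by -1.28 (SE 0.15, adjusted p of 0.019), by -3.11 with normexp without offset and by -0.22 with an offset of 50. The differences of llmg_1240 to llmg_1245 ran from 1.98 to 3.27 with normexp without offset and from 0.14 to 0.20 with an offset of 50. These 5 calls, 4 higher and 1 lower, were the only ones. In the neighbourhood list 4 rose, 0 fell and 14 did not pass, with 6 higher when adjusted over the list alone. Camera gave adjusted p = 2.2e-06 with the preset correlation and adjusted p = 0.048 with an estimated correlation, for a median difference of 0.23. Leaving out wild type replicate 1 gave 40 calls (5 higher and 35 lower), leaving out wild type replicate 2 or replicate 2 of this group gave 0, and leaving out its replicate 1 gave 3, none of them among the 5. The count was 2 with median scaling and with the processed table, and 0 with a normexp offset of 50, with the mean over rows or with Cy3 alone.

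In the IS905 integrant with no density of its own, no feature passed the threshold against the wild type in limma, while 150 had an unadjusted p under 0.05. Among features whose cultures did not overlap with the wild type, the largest positive differences were those of features next to llmg_1239. These were llmg_1242 at 0.93 (SE 0.19) and llmg_1245 at 0.89 (SE 0.15), with adjusted p of 0.206 and 0.193. llmg_0186 differed by -0.94 (SE 0.15, adjusted p of 0.193), by -1.98 with normexp without offset and by -0.18 with an offset of 50. llmg_0187, singled out after its values were seen, differed by -1.16 (SE 0.31, adjusted p of 0.389). It was the 1 call with a block by the number in the source name. A block by replicate number gave 2 calls, both among llmg_1240 to llmg_1245. The labels tie neither number to a shared batch. All 6 features from llmg_1240 to llmg_1245 were higher in both cultures than in both wild-type cultures, by 0.56 to 0.93. In the neighbourhood list 0 rose, 0 fell and 18 did not pass. When adjusted over the list alone 5 were higher and 1, llmg_1238, was lower. Camera gave adjusted p = 5.2e-05 with the preset correlation, and the call was lost with an estimated one (adjusted p = 0.074). The median difference was 0.11. Leaving out IS905 integrant replicate 2 gave 2 calls and leaving out wild type replicate 1 gave 44 (2 higher and 42 lower). A normexp correction without offset gave 5 calls, which were 4 of the 6 features next to llmg_1239 and llmg_0186. The 6 differences ran from 1.31 to 2.57 in that setting and from 0.09 to 0.13 with an offset of 50.

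**Figure D2:**
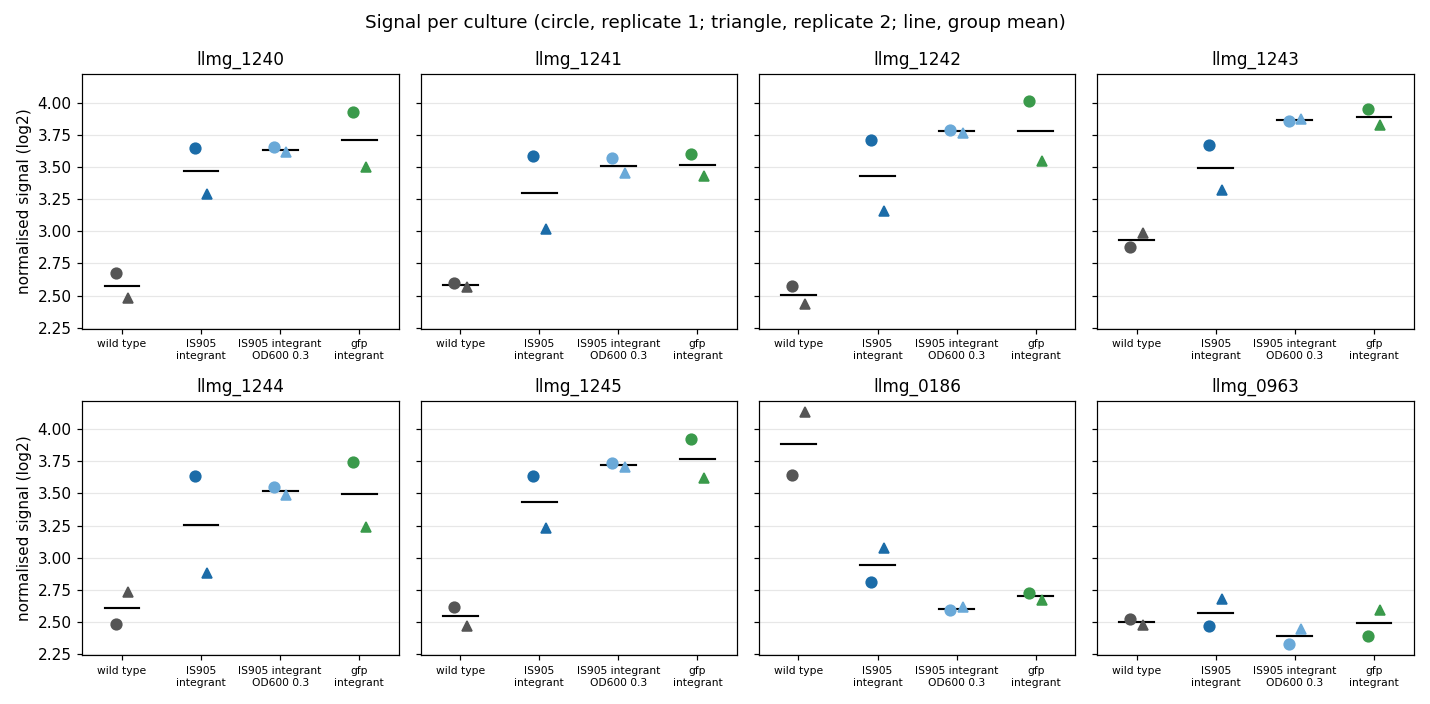
Normalised signal (log2, vertical axis) of 8 features in each culture of the 4 groups (horizontal axis), with circles for replicate 1, triangles for replicate 2 and lines for group means of 2 cultures. llmg_1240 to llmg_1245 are higher in every integrant culture than in both wild-type cultures, llmg_0186 is lower in every integrant culture, and llmg_0963 lies between 2.33 and 2.68 throughout.

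No feature was called alike in all 3 comparisons with the wild type, since 1 of them had no calls. The IS905 integrant at OD600 0.3 and the gfp integrant shared all 5 of their calls, in the same directions. Unchanged groups compared with the same 2 wild-type cultures shared 0 in each of 100 simulations. Such groups gave at most 1 call per comparison there, so this value was all but fixed and says nothing about agreement beyond the shared cultures. Independent lists of these lengths would share 0.0061 higher and 0.00038 lower features. Part of the excess may come from the shared wild-type cultures, which were too few to split. Across features, which are not independent replicates, the covariance of the 2 sets of log2 differences was 0.024, against 0.011 in the simulations. In the other 2 pairs the covariance lay nearer to the simulated value. Between the 2 IS905 integrant groups, which share a genotype, the covariance was 0.0112, against 0.0106 in the simulations. Between the gfp integrant and the IS905 integrant with no density of its own it was 0.0142, against 0.0107. The simulations used a spread pooled over the 4 groups. Covariance due to shared wild-type cultures depends on the spread of the wild type alone. Small excesses over the simulated values therefore cannot be read as agreement beyond the shared cultures. Of all features, 103 were higher in all 6 integrant cultures than in both wild-type cultures and 93 were lower (3.91% and 3.53%), where chance gives 3.57% in each direction.

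The gfp integrant was set against the IS905 integrant to test whether the effects against the wild type differ. No feature passed in limma, and 258 had an unadjusted p under 0.05. The 6 features from llmg_1240 to llmg_1245 differed by 0.22 to 0.39, with 95% confidence intervals that together span -0.28 to 0.77. Camera placed the neighbourhood list higher in the gfp integrant (adjusted p = 3.5e-04, median 0.22), which was lost with an estimated correlation (adjusted p = 0.101) and without IS905 integrant replicate 2 (adjusted p = 0.128). The largest differences without overlap between cultures, chosen after their values were seen, were llmg_1635 at 1.02 (SE 0.41, adjusted p of 0.492) and llmg_1967 at -0.61 (SE 0.12, adjusted p of 0.410).

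Between the IS905 integrant cultures at OD600 0.3 and those with no density of their own, no feature passed in limma and 315 had an unadjusted p under 0.05. The 6 features next to llmg_1239 differed by 0.17 to 0.37. The neighbourhood list had a median difference of 0.15 (camera adjusted p = 0.043), lost with an estimated correlation (adjusted p = 0.296), without IS905 integrant replicate 2 (adjusted p = 0.768) and without replicate 2 of the cultures at OD600 0.3 (adjusted p = 0.240). llmg_1635, also chosen after its values were seen, stood at 5.89 at OD600 0.3 against 4.44, a difference of 1.45 (SE 0.41, adjusted p of 0.327). It was called with a block by replicate number, while a block by the number in the source name gave 0 calls. Nothing in the labels ties either number to a shared batch. The count of calls was 1 with a normexp offset of 50, 1 without IS905 integrant replicate 1 and 3 without replicate 1 of the cultures at OD600 0.3.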

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

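The tests of explanations in this part were chosen after the values were seen. The shift of the llmg_1239 neighbourhood differed between integrant groups. It was larger in the gfp integrant than in the IS905 integrant (camera adjusted p = 0.00035) and larger in the IS905 integrant at OD600 0.3 than in the IS905 integrant with no density of its own (camera adjusted p = 0.043). Neither held with an estimated correlation, or without IS905 integrant replicate 2. The second was also lost without replicate 2 of the cultures at OD600 0.3.

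IS905 integrant replicate 2 carried the smaller difference: llmg_1240 to llmg_1245 stood on average 0.52 (log2) above the wild-type mean in this culture and 1.05 above it in the other 5 integrant cultures. A narrower range of the summarised feature values may account for this. The brightest 5% of features outside the neighbourhood stood only 0.63 times as high above the median as in the other 5 cultures, whose own ratios ran from 0.994 to 1.12. The raw columns of this culture were not narrower: their 99th percentile was 3.79 (Cy3) and 2.73 (Cy5) times the median, against 1.98 to 4.55 over all samples. The narrower range thus appeared after normalisation and the summary over rows and dyes, and its cause was not tested. In the same culture llmg_0186 stood at 3.08, against 2.59 to 2.81 in the other 5, and no explanation for this was tested. Density was not tested, since this group has none of its own in the labels.

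The higher signal of llmg_1240 to llmg_1245 in all 6 integrant cultures was weighed against 2 technical explanations. Of these 6 features 4 passed at OD600 0.3 and in the gfp integrant, and 0 in the other IS905 integrant group. A signal of a single dye was excluded, because the lowest integrant culture lay above the higher wild-type culture in both dyes, by 0.39 in the dye with the smaller gap. For a few aberrant rows, the share of rows was counted: 86.1% of the 36 rows had all 6 integrant cultures above both wild-type cultures. This share cannot decide the question. The 6 features were picked by medians over these rows, which a few rows hardly move, so a high share was all but fixed. The integration and the 3 deletions were not separated, as each integrant carries both. The higher signal may follow from either, as an untested hypothesis.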

How the results depend on the processing

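Of the alternatives, a normexp offset of 50 was chosen after the data were seen, and slide or array as a block was not run because no file gives one. Very bright single spots were used to ask which samples shared an array: of 53, 27 were bright in both dyes of 1 culture and 0 in different cultures. If the dyes of a culture share an array, a within-array loess changes their difference and not their mean. No loess curve was fitted within arrays. Instead, the log signals of both dyes of a culture were averaged, and these means were quantile normalised. Averaging the dyes before normalisation, and leaving out the dimmest 25% of features, kept all counts. Such averaging does not test a within-array loess. llmg_1240 to llmg_1245 were higher than the wild type in all 414 values over 23 alternatives, and llmg_0186 lower in all 69, but the sizes moved widely: from 0.093 to 4.63 and from -4.72 to -0.18 (log2). These features were picked from the same data, and the alternatives reprocess the same 8 cultures. The tally therefore shows only that the sign did not depend on the processing, and adds no independent support. The smallest sizes came with an offset of 50 and the largest with the processed table, whose scale is stretched. llmg_0963 changed sign in the gfp integrant with a normexp offset of 50 (0.00024), median scaling (0.013), the mean over rows (0.0067), Cy5 alone (0.017), the processed table (0.0022) and without single cultures (-0.106 to 0.090). It did so without single cultures in the IS905 integrant too (-0.030 to 0.176). The cause of the changes below was not tested.

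Counts in the order IS905 integrant, IS905 integrant at OD600 0.3, and gfp integrant, each against the wild type, then features alike in all 3, were 0, 5, 5 and 0 as reported. They were 5, 7, 9 and 5 with normexp without offset, 0, 0, 0 and 0 with an offset of 50, 0, 2, 2 and 0 with median scaling, and 4, 6, 6 and 4 with cyclic loess. With the mean over rows they were 0, 0, 3 and 0, with Cy3 alone 0, 0, 0 and 0, and with Cy5 alone 1, 3, 2 and 1. The 16 samples with dye and culture gave 7, 10, 8 and 4, trend and robust variance 1, 5, 8 and 1, and values from the processed table gave counts of 0, 2, 2 and 0. Leaving out single cultures gave 0 to 44, 0 to 40, 0 to 36 and 0 to 33. A lone culture was then assumed to vary like the other groups. The gfp integrant against the IS905 integrant kept 0 calls under all alternatives. The IS905 integrant at OD600 0.3 against the other IS905 cultures had 1 with an offset of 50, 1 with the replicate block, and 0 to 3 without single cultures.

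Replicate numbers are shared between groups, but nothing in the labels ties them to a shared batch, and with 2 numbers the block is only a hint. Deviations of cultures with the same number correlated at 0.23 to 0.49 between integrants and -0.27 to -0.17 with the wild type, while the number in the source name gave 0.17 to 0.49 throughout. With the replicate block the counts were 2, 7, 6 and 2. That block called llmg_1635 at OD600 0.3, both against the wild type and against the other IS905 cultures. With the block by source number the counts were 1, 9, 9 and 1, where the 1 call in the IS905 integrant was llmg_0187 (adjusted p of 0.00095). At OD600 0.3 and in the gfp integrant, this block called all 6 features from llmg_1240 to llmg_1245 and llmg_0187, but not llmg_1635.

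The neighbourhood list lost its call with an estimated correlation in the IS905 integrant (adjusted p = 0.074), between the gfp and IS905 integrants (adjusted p = 0.101) and between the IS905 groups (adjusted p = 0.296), where cyclic loess also ended it (adjusted p = 0.107). Without single cultures, its adjusted p ran from 4.8e-06 to 0.128 between the gfp and IS905 integrants and from 0.0016 to 0.768 between the IS905 groups. A signal range of only 1.98 to 4.55 between the 99th percentile and the median limits what small differences can show.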

Other observations

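The blocks in this part were chosen after the values were seen. Blocks of 10 consecutive locus numbers with at least 5 measured members, 254 in all, were tested with camera at the preset correlation. Besides the features next to llmg_1239, llmg_0181 to llmg_0190 stood lower than the wild type in each integrant group, with median differences of -0.44 in the IS905 integrant, -0.41 at OD600 0.3 and -0.39 in the gfp integrant (adjusted p of 1.6e-06, 6.3e-05 and 0.00033). Of the 10 members of this block, 10, 8 and 8 were lower in these groups, in the same order. None of the 3 differences held with an estimated correlation (adjusted p of 0.865, 0.996 and 0.989). Without wild type replicate 2 they were -0.26, -0.18 and -0.19 (adjusted p of 0.0043, 0.222 and 0.202), and without IS905 integrant replicate 2 the first was -0.27 (adjusted p of 0.0095). llmg_2371 to llmg_2380 were lower in the IS905 integrant than in the wild type (median -0.33, 10 of 10 members, adjusted p of 1.4e-06), and higher at OD600 0.3 than in the other IS905 cultures (median 0.31, 10 of 10 members, adjusted p of 0.00065). Neither held with an estimated correlation (adjusted p of 0.865 and 0.988). Without IS905 integrant replicate 2 these differences were -0.15 and 0.14, with adjusted p of 0.054 and 0.292, and without replicate 2 of the cultures at OD600 0.3 the second was 0.25 (adjusted p of 0.0503).

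The adjacent block llmg_2361 to llmg_2370 differed in the same directions, by -0.35 (adjusted p of 0.0030) and 0.31 (adjusted p of 0.014). Without IS905 integrant replicate 2 these were -0.23 and 0.25, still past the threshold (adjusted p of 0.030 and 0.026). The first was lost without wild type replicate 1 (-0.13, adjusted p of 0.324), and the second without IS905 integrant replicate 1 (adjusted p of 0.088) or replicate 2 at OD600 0.3 (adjusted p of 0.111). llmg_2531 to llmg_2540 stood lower than the wild type in the IS905 integrant (-0.18, adjusted p of 0.0050) and the gfp integrant (-0.19, adjusted p of 0.016), and llmg_2251 to llmg_2260 in the gfp integrant (-0.24, adjusted p of 0.016). llmg_1291 to llmg_1300 stood higher in the IS905 integrant (0.14, adjusted p of 0.032). Without wild type replicate 2 these 4 differences were -0.02, -0.06, -0.04 and 0.07, with adjusted p of 0.877, 0.965, 0.927 and 0.601. The smallest adjusted p of any block with an estimated correlation was 0.865.

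llmg_0186 was the only feature called lower in 2 comparisons with the wild type. It stood at 3.64 and 4.13 in the wild-type cultures and between 2.59 and 3.08 in the 6 integrant cultures. Whether it is one of the deleted genes was not tested, because the tables used here do not pair locus tags with the names celB and ptcC.

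Over all features, the signals of the 2 wild-type cultures correlated at 0.813. Wild type replicate 1 correlated more closely than that with every integrant culture, at 0.832 to 0.867. For wild type replicate 2 the correlations with integrant cultures ran from 0.680 to 0.811. Every comparison with the wild type rests on these 2 cultures, and the cause of their difference was not tested. Wild type replicate 2 also stood apart in the as- features: their 95th percentile was 3.68 there and between 2.88 and 3.02 in the other 7 cultures. The larger counts of calls without wild type replicate 1 rest on this culture alone as the wild type. Of those 44, 40 and 36 calls (IS905 integrant, OD600 0.3 and gfp integrant), 5, 4 and 4 were as- features, all lower than in the wild type, out of 59 as- features measured.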
